A study of Mus musculus with 4 samples.

How the data were processed

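Nuclear RNA from frozen whole hypothalamus of mice aged about 18 months was profiled in 4 samples, 2 labelled control and 2 labelled transplanted. Per the labels' protocols, nuclei were isolated with a commercial kit and libraries were made with the Chromium 3' chemistry, version 3.1. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, per the file headers, which name Cell Ranger. The submitters' processing notes name Cell Ranger 5.0.1 and the human build GRCh38, while the gene identifiers in the files are those of mouse. The mouse build is not given in the sources used here, so no coordinates are printed. Of the 32285 gene identifiers in the files, 32158 are in the GENCODE M21 table. The files hold 78 symbols that are shared between identifiers, and these genes were kept apart by identifier. How the authors chose barcodes is not given in the sources used here. The lowest UMI count per barcode was 500 or 501 in each matrix.

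Samples were grouped by the treatment label, and replicates were numbered in accession order. Some titles join 2 animal codes, and whether those nuclei were pooled from 2 animals is not stated. P-values therefore measure only the spread between these samples, which may be technical. Before any test, the matrices were compared in pairs by their barcodes, by the profile of each common barcode and by their gene totals. The squared difference of 2 gene totals was divided by its binomial sampling variance, over genes with at least 20 counts in the pair, so that 1 stands for sampling noise. The same ratio was taken over single gene and nucleus entries. Genes were called within a pair by a chi-square test against sampling noise, and again against the smaller noise between single entries, at an adjusted p of 0.05. Profile correlations were taken over 400 common barcodes per pair.

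Nuclei with at least 300 genes and at most 5% mitochondrial counts were kept, a filter that removed no barcode. Doublets were called per matrix with scrublet in scanpy 1.11.5. It called 53 of 12329 nuclei (0.430%). The rate was 0.125% in control replicate 1, 0.0995% in transplanted replicate 1, 1.16% in control replicate 2 and 0.883% in transplanted replicate 2. It did not work as a doublet filter in the replicate 1 matrices, where doublets are in effect still present. In the replicate 2 matrices doublets may also remain. The 12276 nuclei left were normalized to 10000 counts, log-transformed, reduced to 40 principal components over 3000 variable genes and clustered with leiden at resolution 1 on 20 neighbours (igraph 0.11.9). A cluster received a class name when at least 3 of that class's markers, fixed before the data were examined, were among its 10 leading genes by fold. A leading gene needed at least 50 UMIs, and folds carried a prior of 5 CPM. A remaining cluster was named a neuron when at least 6 of 12 neuron markers were over 2-fold above the mean of the clusters already named and fewer than 2 markers of any other class were among its leading genes. The names mean neuron-like, astrocyte-like and so on, and are written without that ending. Of the 19 neuron clusters, 3 held more markers of another class than of neurons among their 10 leading genes, and the counts of genes in neurons and of lists between classes were repeated without them.

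Counts were summed per sample over all nuclei and per class with at least 20 nuclei in every sample, since nuclei are not replicates. The sums were tested with edgeR 4.0.16 (quasi-likelihood fit, TMM, low-count filter, transplanted against control without a block) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Class shares were tested in the same tool with the total of nuclei as offset. The 27 gene lists, 496 genes in all, were fixed before the data were examined and tested with camera in limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested genes. An interaction fit asked whether the difference between labels itself differed between neurons and astrocytes or oligodendrocytes. Levels are given as CPM, the counts of a gene scaled to a common total per sum. A count of 0 is given with the level that 3 counts would have. Intervals are exact at 95% and cover counting error only.

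Because each pair of matrices turned out to hold 1 set of nuclei, levels are given as the mean of the 2 deposits per distinct library, rounded to whole counts, and mean ± SD runs over the 2 distinct libraries. The comparison of fixed lists between cell classes was added after the data were seen. It fitted class and library in edgeR on these means, each class against the average of the 5 others on the log scale, and a member is called higher or lower when it passed that test. Named genes followed a rule fixed before the data were examined. It took the 10 smallest p per direction among genes that passed and whose samples did not overlap (3 in the smaller classes). A direction with fewer than 5 was filled to 5 by unadjusted p (to 3 in the smaller classes), and up to 4 members of a fixed list were those with the smallest p where that list is described. Hypothalamic peptide genes, Gfap, Mbp and sex-linked genes were always included, and unnamed gene models were left out.

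The tests were tried on simulated independent samples with 200 changed genes, which does not describe matrices that hold the same nuclei. In the sum over all nuclei, 98.0% of 4-fold and 23.8% of 2-fold changes were called, with 15904 genes and a dispersion of 0.05. In neurons, 98.0% of 4-fold and 14.0% of 2-fold changes were called. The changed genes were drawn only from genes above a floor in mean counts, so these rates do not hold for genes with few counts. A difference between the 2 libraries was also simulated in neurons, at a dispersion below 0.05. There the fit without a block called 0% of 4-fold changes and the fit with the replicate as a block called 100%. Because the noise was smaller, the 100% cannot be set against the 98.0%. A block separates the samples whose titles join 2 animal codes from those with 1, which here is the replicate number. Alternatives were another normalization (RLE), DESeq2 1.42.0, no low-count filter, the replicate block, each sample left out, every barcode kept, stricter nuclei, doublets kept, thinning to one depth, resolution 2, an estimated correlation and fry. For an uncalled value the sign was not read as a direction.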

Results

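The study asked how the hypothalamus of mice about 18 months old differs after transplantation of hypothalamic stem cells derived from human pluripotent stem cells. Single-nucleus RNA profiles were deposited for 2 samples labelled control and 2 labelled transplanted. The matrix labelled control replicate 1 held 4008 nuclei and 8779880 UMIs, and that labelled control replicate 2 held 2150 nuclei and 4924563 UMIs. The matrix labelled transplanted replicate 1 held 4020 nuclei and 8844994 UMIs, and that labelled transplanted replicate 2 held 2151 nuclei and 4891189 UMIs. The median nucleus had 1813, 2049, 1819.5 and 2030 UMIs in the same order. Mitochondrial counts did not exceed 0.808% of any nucleus.

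The matrices labelled control and transplanted held the same nuclei. Of the 4008 barcodes of control replicate 1, 3997 (99.7%) were also in transplanted replicate 1, and of the 2150 barcodes of control replicate 2, 2144 (99.7%) were also in transplanted replicate 2. Every other pair of matrices had 4 barcodes in common. The profile of a common barcode correlated between its 2 deposits with a median of 0.956 in the first pair and 0.966 in the second, against 0.480 and 0.647 for randomly paired barcodes. Total UMIs per nucleus correlated at 0.9997 in both pairs on the log scale. Gene totals differed by 0.236 and 0.240 times the sampling noise, which is less than 2 independent samplings give. Pairs of matrices from different replicate numbers differed by 19.3 to 19.4 times that noise. Against sampling noise, 0 genes were called between the 2 deposits of either pair. Against the smaller noise between single entries, 10 were called in the first pair and 3 in the second, and of 14796 genes compared in both, 0 were called in both with the same direction and 49.5% had the same sign. Among the 10 was the gene model Gm45184, with 14 UMIs under the control label and 35 under the transplanted label, against 12 and 17 in the second pair. The 4 matrices therefore held 2 distinct libraries, each deposited under both labels. They are called library A (the libraries labelled control replicate 1 and transplanted replicate 1) and library B (the libraries labelled control replicate 2 and transplanted replicate 2), and levels given with n = 2 count each as 1 sample. The tests between labels that follow took the 4 matrices as deposited, so their samples are not independent. Which label belongs to which library cannot be decided from the counts, and no effect of transplantation can be estimated from these files.

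**Figure D1:**
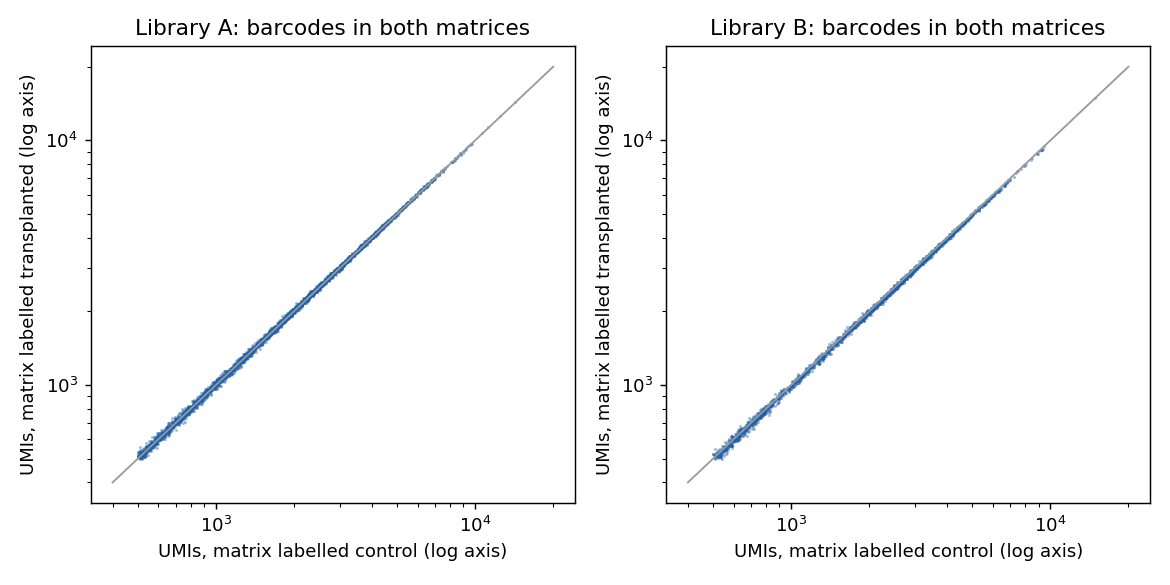
UMIs per nucleus in the matrix labelled transplanted (y axis, log scale) against those of the same barcode in the matrix labelled control (x axis, log scale), for library A (3997 barcodes) and library B (2144 barcodes). Each point is 1 barcode and the grey line marks equal values, which the points follow along their whole range.

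As deposited, no gene passed the test of the libraries labelled transplanted against those labelled control. Over all nuclei, 0 of 15904 genes passed edgeR's quasi-likelihood test, 1 had an unadjusted p under 0.05, and DESeq2 called 0. That gene, picked after its values were seen, was Gm45184 at 3.78 CPM against 2.01 CPM (log2 difference 0.94). The smallest unadjusted p among named genes that were higher in the libraries labelled transplanted belonged to Gli1 (ENSMUSG00000025407), a transcription factor of hedgehog signalling. It stood at 4.26 CPM against 3.01 CPM, a log2 difference of 0.50 with a standard error of 0.24 and an edgeR adjusted p of 0.99999, and did not pass. Among those that were lower, Bend5 (ENSMUSG00000028545) stood at 2.32 CPM against 3.57 CPM, a log2 difference of -0.62 with a standard error of 0.26 and an edgeR adjusted p of 0.99999. The others filled in by the rule were Mcat, Shisa3, Tifa and Zbtb18 on the higher side and Larp7, Spc24, Adgrg6 and Degs2 on the lower, and none passed. Samples of the 2 labels did not overlap for 6.30% of genes, where chance gives 33.3% for independent samples. An exact permutation test of 2 against 2 cannot go below p = 0.33.

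Each cell class gave the same count. In neurons 0 of 15247 genes passed edgeR's test, in astrocytes 0 of 4164, in oligodendrocytes 0 of 4436, in oligodendrocyte precursors 0 of 2766, in tanycytes 0 of 1867 and in microglia 0 of 835. An unadjusted p under 0.05 was found for 0 genes in each of these classes, and DESeq2 called 0 in each. Neurons without the 3 clusters that other classes' markers led, a check chosen after the data were seen, also gave 0. The 10 always-named peptide genes that could be tested had log2 differences between labels from -0.07 to 0.06 in neurons, and none passed. Agrp, which drives feeding, stood at 37.5 CPM in the libraries labelled transplanted and 36.0 CPM in those labelled control. Pomc, the precursor of the satiety peptide alpha-MSH, stood at 6.77 CPM and 6.84 CPM, Npy at 8.45 CPM and 8.93 CPM, Hcrt at 58.0 CPM and 57.6 CPM, and Pmch at 61.3 CPM and 60.2 CPM. Oxt, Avp, Trh, Crh and Sst had log2 differences of 0.06, 0.02, 0.05, 0.02 and 0.03. Gfap in astrocytes, a marker of reactive astrocytes, stood at 74.5 CPM and 62.7 CPM (log2 difference 0.25, standard error 0.48). Mbp in oligodendrocytes, which codes for myelin basic protein, stood at 2539 CPM and 2454 CPM. Since both labels hold the same nuclei, the counts of 0 were fixed by the files and say nothing about an effect of transplantation. The fit with the replicate as a block called 3 genes over all nuclei and 1 in neurons, each with a log2 difference of 0.01.

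No fixed gene list and no class share passed its test between labels. In camera tests in limma, 0 of 27 lists passed over all nuclei, with list medians of log2 differences from -0.06 to 0.05, and the smallest adjusted p was 0.885. In neurons 0 of 26 passed, with medians from -0.10 to 0.07 and a smallest adjusted p of 0.214, for neural stem cell and neurogenesis genes, which with the interferon-stimulated genes made up the 2 lists at an unadjusted p under 0.05. None passed among 13 lists in astrocytes, 12 in oligodendrocytes, 8 in oligodendrocyte precursors, 5 in tanycytes and 2 in microglia, where 0 lists had an unadjusted p under 0.05. With an estimated correlation and with fry in limma, 0 lists passed in any of these sums. Of the list members, 0 passed over all genes tested and 0 passed adjusted over the list alone. Over all nuclei, the median was 0.01 for the neuropeptides, 0.05 for the reproductive axis and 0.03 for cell senescence genes. The interaction fit found 0 of 7256 genes whose difference between labels itself differed between neurons and astrocytes or oligodendrocytes, with 3 (Serpini1, Clstn2, Tfcp2) and 2 (Fam228a, Mctp1) genes at an unadjusted p under 0.05, named after their values were seen. For class shares, 0 of 6 classes passed edgeR's test (adjusted p of 0.992 for each), 0 had an unadjusted p under 0.05, and DESeq2 called 0. Leaving out control replicate 2 gave 1 gene over all nuclei (Hbb-bs), 1 in astrocytes (Col25a1) and 10 lists. Leaving out transplanted replicate 2 gave the same 2 genes in the opposite direction, 1 gene in oligodendrocyte precursors (Malat1), 1 in the interaction (Col25a1) and 10 lists, since libraries A and B then weigh unequally in the labels, while leaving out control replicate 1 or transplanted replicate 1 gave 9 and 8 lists.

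Neurons made up 72.1% ± 4.56 (SD, n = 2 distinct libraries) of nuclei, with 75.3% in library A and 68.9% in library B. Oligodendrocytes made up 11.4% ± 2.87, astrocytes 8.47% ± 1.28, oligodendrocyte precursors 3.37% ± 0.0111, tanycytes 2.35% ± 0.502 and microglia 1.80% ± 0.583 (SD, n = 2 each). A cluster led by the haemoglobin genes Hbb-bs, Hba-a2 and Hba-a1, of 9 to 15 nuclei per matrix, remained unnamed. Neurons formed 19 of the 25 clusters. Cluster 1, the largest, had Pmch, Ebf1 and Ebf2 among its leading genes and held 13.5% ± 1.46 of nuclei (SD, n = 2). A UMI of Pmch was found in 4.98% of neurons in library A and 3.44% in library B, fewer nuclei than cluster 1 held. Among the leading genes of other clusters were Npy, Pomc and Esr1 (cluster 6), Hcrt, Gal and Nts (cluster 7), Vip, Vipr2 and Prok2 (cluster 10), Cartpt, Lepr and Glp1r (cluster 18), Avp, Oxt and Sim1 (cluster 21) and the histamine enzyme gene Hdc (cluster 24). The same nucleus fell in the same cluster in both deposits for 99.7% of nuclei in library A and 99.6% in library B.

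**Figure D2:**
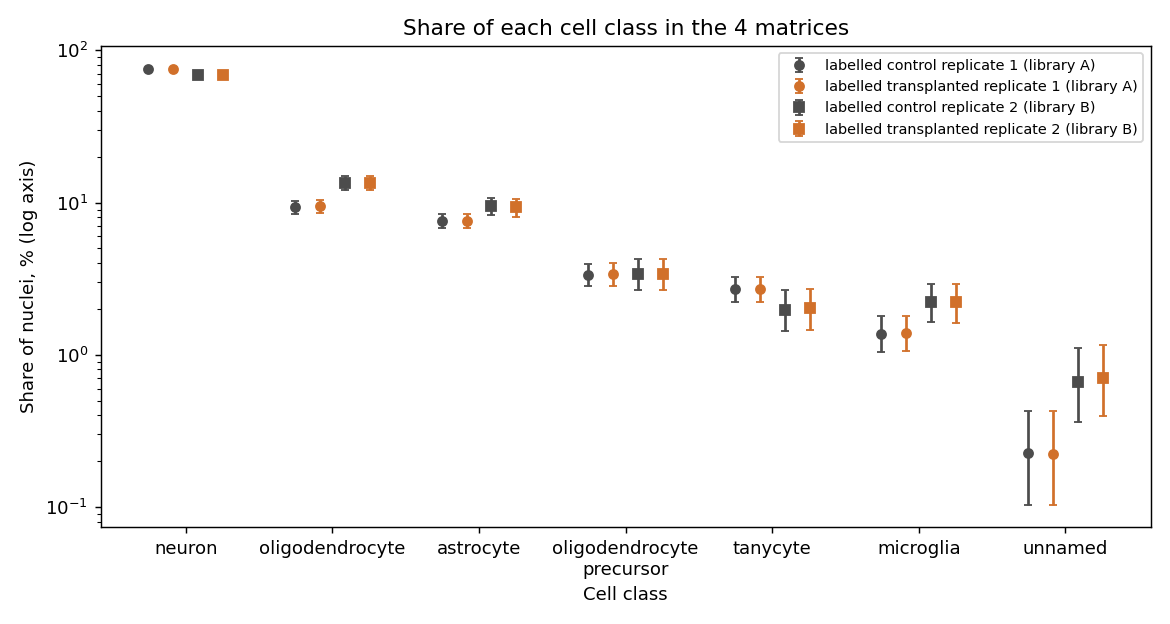
Share of nuclei in each cell class (y axis, percent, log scale) in the 4 matrices, by label (colour) and distinct library (marker shape). Points are shares and bars are exact 95% binomial intervals, and within a library the intervals of the 2 labels overlap in every class.

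Peptide genes averaged over all neurons stood at different distances from their level in glia. Pmch (ENSMUSG00000035383), the precursor of melanin-concentrating hormone, was at 59.4 CPM ± 21.4 in neurons, 47.5 CPM ± 4.84 in astrocytes and 32.8 CPM ± 6.11 in oligodendrocytes (SD, n = 2 distinct libraries). Hcrt (ENSMUSG00000045471), the precursor of the orexins, was at 55.9 CPM ± 34.0 in neurons, 51.8 CPM ± 17.3 in astrocytes and 63.6 CPM ± 30.9 in oligodendrocytes (SD, n = 2). A UMI of Hcrt was found in 4.40% of neurons and 5.57% of oligodendrocytes in library A and in 2.32% and 2.97% in library B. The median neuron had 2273.5 UMIs in library A and 2618.75 in library B, and the median oligodendrocyte 670 and 683.25. Agrp (ENSMUSG00000005705) was at 36.6 CPM ± 0.650 in neurons, 41.0 CPM ± 9.98 in astrocytes and 16.4 CPM ± 3.05 in oligodendrocytes (SD, n = 2). Gal, which codes for galanin, was at 77.2 CPM ± 9.01 in neurons, 16.5 CPM ± 0.671 in astrocytes and 25.7 CPM ± 16.2 in oligodendrocytes (SD, n = 2). Agrp was found in 8.67% of neurons and 1.06% of oligodendrocytes in library A and in 9.65% and 1.22% in library B. In libraries A and B it was found in 3.95% and 3.26% of astrocytes, 2.59% and 4.86% of precursors, and 5.07% and 10.6% of tanycytes. In microglia it was found in 1.80% in library A and 0% in library B, which allows up to 93.6 CPM there. Trh, the precursor of thyrotropin-releasing hormone, was at 25.3 CPM ± 12 in neurons (SD, n = 2) and had 0 UMIs in oligodendrocytes, which allows up to 10.7 CPM in library A and 13.9 CPM in library B. Gnrh1 (ENSMUSG00000015812) was found in 0.149% of neurons and 0.132% of oligodendrocytes in library A and in 0.239% of neurons in library B. Kiss1 had 0 UMIs in neurons of library A, which allows up to 0.377 CPM, and was found in 0.0342% of neurons in library B. Uty, on the Y chromosome, was at 289 CPM ± 65.0 in neurons (SD, n = 2).

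The fixed lists were then compared between cell classes, a comparison chosen after the data were seen. The classes were built from the same counts, so the myelin list in oligodendrocytes (16 of 16 tested members higher), the homeostatic microglia list in microglia (9 of 9) and the receptor list in neurons (22 of 23) are no independent evidence. With the preset correlation, 27 of 102 pairs of a list and a class passed, over 6263 genes. With an estimated correlation 1 passed, the myelin list in oligodendrocytes (adjusted p = 0.0226). The low-count filter can admit a list member through the class where it is high. Without that filter, at the preset correlation, 22 of the 27 passed. The circadian clock list was higher in astrocytes, with 12 of 13 tested members higher than the average of the other classes (camera in limma, adjusted p = 9.49e-05, and adjusted p = 0.133 with an estimated correlation). Rorb (ENSMUSG00000036192), a nuclear receptor, stood at 1168 CPM ± 228 in astrocytes and 253 CPM ± 57.5 in neurons (SD, n = 2). Per3 (ENSMUSG00000028957), a period gene, stood at 605 CPM ± 232 in astrocytes and 156 CPM ± 72.4 in neurons (SD, n = 2). The cholesterol synthesis list was higher in astrocytes for 5 of 6 tested members, of 17 on the list (adjusted p = 0.0223, and adjusted p = 0.199 with an estimated correlation). Msmo1 (ENSMUSG00000031604), a sterol oxidase gene, stood at 163 CPM ± 26.0 in astrocytes and 21.5 CPM ± 0.518 in neurons (SD, n = 2). The list of growth factors and receptors was higher in astrocytes for 10 of 14 tested members, of 20 on the list (adjusted p = 0.00357, and adjusted p = 0.133 with an estimated correlation). Fgfr3 (ENSMUSG00000054252) stood at 303 CPM ± 3.58 in astrocytes and 1.21 CPM ± 0.285 in neurons (SD, n = 2). The list of interferon-stimulated genes was higher in tanycytes for 7 of 9 tested members, of 26 on the list (adjusted p = 0.000313, and adjusted p = 0.125 with an estimated correlation). Ifi27 stood there at 150 CPM ± 25.2 against 4.82 CPM ± 1.14 in neurons (SD, n = 2), from about 14 UMIs in library A and 8 in library B, as rounded means of the deposits. The interferon list was also higher in microglia, for 3 of 9 tested members (camera in limma, adjusted p = 0.00666, and adjusted p = 0.177 with an estimated correlation).

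**Figure D3:**
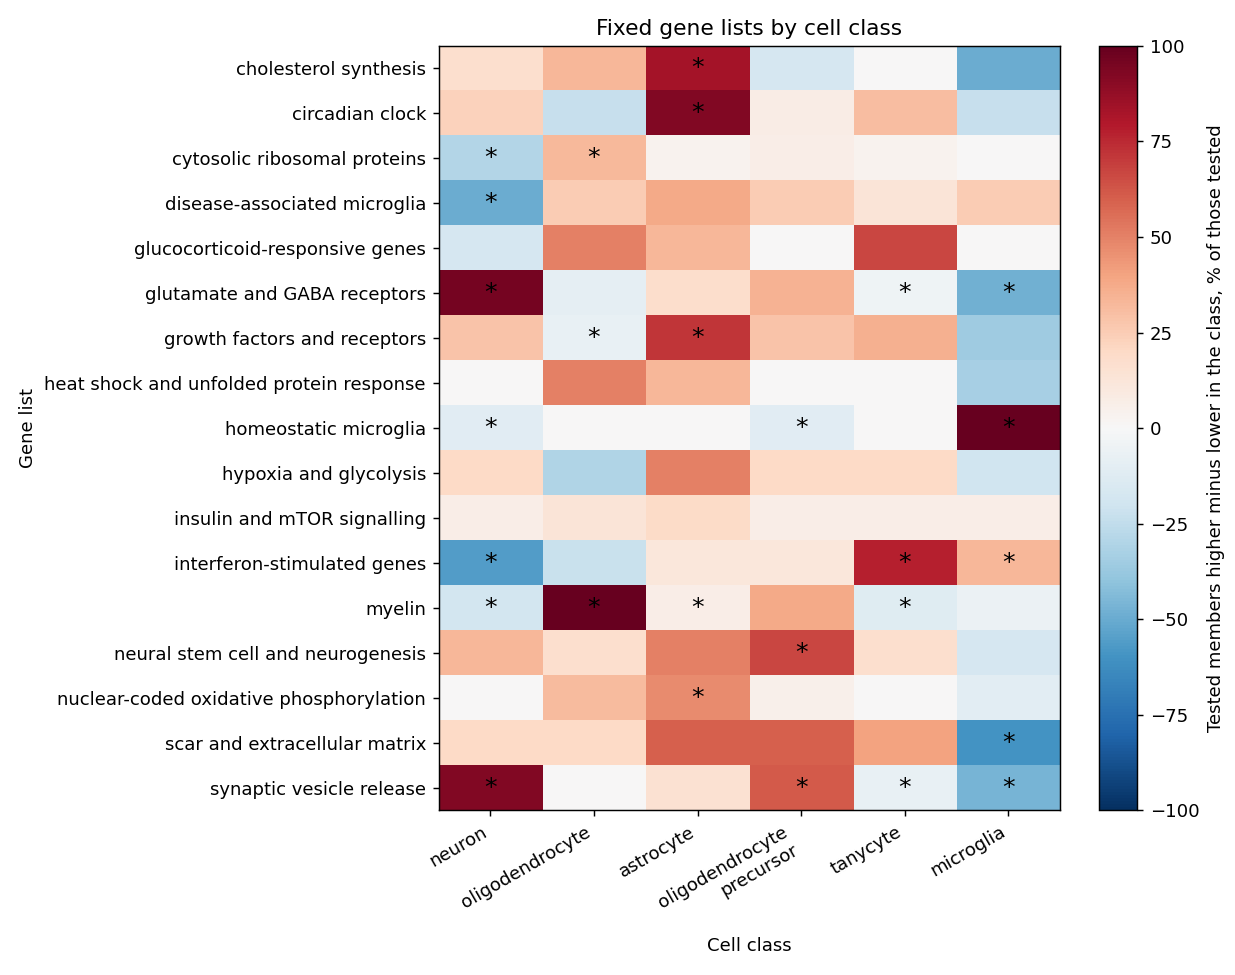
Number of tested list members higher minus lower in a cell class than in the average of the other classes, as a percentage of those tested (colour), for the fixed lists (rows) and classes (columns), n = 2 distinct libraries. Stars mark the 27 pairs past an adjusted p of 0.05 in camera at the preset correlation, of which 1, the myelin list in oligodendrocytes, passed with an estimated correlation.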

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

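A count was taken as unmoved when it equalled the main count or lay within 1.5-fold of it. By that rule, of 131 values of the main results under alternatives, 117 did not move and 14 moved. The 27 list calls between classes, for example, became 21 with stricter nuclei and were taken as unmoved. For named genes, 950 of 950 values stayed uncalled. Both labels hold the same nuclei, so values that stayed uncalled say nothing about an effect of transplantation. The replicate block called 3 genes over all nuclei (Lingo2, Kcnip4 and Cntnap2, with log2 differences of 0.01 and the smallest adjusted p of 6.41e-05 for Cntnap2) and 1 in neurons (Cntnap2, adjusted p = 0.0072), named here after their values were seen. The replicate numbers come from accession order, and deviations from the group means of same-numbered samples correlated at 0.968 across 10871 genes, because these samples hold the same nuclei. Leaving out 1 sample weights libraries A and B unequally between the labels, so its calls follow from that construction, and the lone sample is assumed to vary like the others. Leaving out each sample gave 0 to 1 genes over all nuclei (Hbb-bs, log2 difference 2.35 without control replicate 2 and -2.45 without transplanted replicate 2), 0 to 1 in astrocytes (Col25a1, log2 difference 3.22 and -3.90), 0 to 1 in oligodendrocyte precursors (Malat1, log2 difference -0.55 without transplanted replicate 2), 0 to 1 in the interaction (Col25a1) and 8 to 10 gene lists. The comparison of lists between classes, with alternatives chosen after the data were seen, gave 54 calls of 162 without the low-count filter, which tests more genes and lists. Among these 54 were 22 of the 27 reported calls. With an estimated correlation there was 1 call, and 0 calls reversed. Keeping every barcode and keeping doublets are one setting, since the filters remove no barcode.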

Other observations

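The tests of barcode collisions, of different nuclei under one barcode and of independent nuclei from one tissue were chosen after the overlap was seen, as were the comparison between cell classes, the genes named for libraries A and B and the limit of 0.1 used there. Precursors of oligodendrocytes carried RNA of genes of the vesicle release list that is also abundant in neurons. Rims1, an active zone gene, stood at 728 CPM ± 58.5 in precursors and 916 CPM ± 52.0 in neurons, and Unc13c at 466 CPM ± 50.6 and 223 CPM ± 4.30 (SD, n = 2 distinct libraries). The list was higher in precursors for 8 of 13 tested members (camera in limma, adjusted p = 0.0463, and adjusted p = 0.355 with an estimated correlation). Cytosolic ribosomal protein genes were lower in neurons for 9 of 31 tested members, of 47 on the list (adjusted p = 0.00207, and adjusted p = 0.177 with an estimated correlation). In oligodendrocytes they were higher for 10 of 31 (adjusted p = 0.0463, and adjusted p = 0.311 with an estimated correlation). Doublets were in effect not removed in library A and may remain in library B. Part of such levels in small classes may therefore be nuclei of 2 types, which was not tested. Keeping every barcode gave 28 list calls, 25 of them among the 27. That setting only returns the 53 called nuclei, so it decides nothing on doublets that were not called.

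The matrices labelled control and transplanted share nearly all barcodes. Chance collisions are argued against by the 2144 common barcodes of the smaller pair, and different nuclei under one barcode by profile correlations that exceed those of random pairs by at least 0.319. Independent nuclei from one tissue would differ by at least the sampling noise, and the larger of the 2 ratios was 0.240. The level set beforehand for 2 read sets of one library was met. The ratio to sampling noise was under 1 in both pairs. It differed by at most 0.0174 between single entries and gene totals, as shared molecules counted from different reads would give. Of the UMIs under the control label, 84.5% and 82.9% were matched in the same nucleus and gene under the transplanted label. Randomly paired barcodes gave 25.4% and 24.6%. Other ways for 1 library to give 2 sets of counts were not tested. The share of genes called in both pairs with one direction was 0%, which decides nothing on an effect of transplantation, since both labels hold the same nuclei.

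Peptide RNA in glial nuclei could be free RNA taken up by every droplet. Of the 6 most abundant peptide genes, 50% lay within 2-fold over astrocytes, oligodendrocytes and precursors, which just meets the level set beforehand. The lowest of the 3 glial counts was under 20 UMIs for each of them, down to about 3 for Gal in precursors, so the counts are too few to decide. That minimum of 20 UMIs was not part of the level set beforehand. No biological explanation was tested.

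Of 4105 genes at 50 CPM or more in neurons of library A or library B, 57 were over 2-fold apart between them. Mettl23 stood at 152 CPM in library A and 35.8 CPM in library B, Hcrt at 80.0 CPM and 32.0 CPM, Gas5 at 15.8 CPM and 54.9 CPM, and Snhg11 at 18986 CPM and 8391 CPM, while the nuclear RNA Malat1, under 2-fold apart and so not among the 57, stood at 18412 CPM and 36376 CPM and mitochondrial RNA made up 0.0119% and 0.0176% of all counts under the control label. Thinning to one depth gave 58 genes, a drop of -1.75%. It scales all genes of a library alike and moved 0 of the 4105 log2 ratios by more than 0.1, so thinning decides nothing on depth. Mean UMIs per neuron in library B were 1.10 times those in library A. The intervals for counting error lay apart for 57 of the 57 genes. At these summed counts, any gene picked at 50 CPM or more and over 2-fold apart would have such intervals. The count therefore follows from the selection and is no separate test. Effects of depth remain open. Weighting 15 neuron clusters equally moved 995 log2 ratios by more than 0.1 and gave 56 genes against 56 before, 44 of them shared, a drop of 0%, which argues against a different mix of these clusters as the whole cause. With 1 library of each kind, differences between animals, pools and preparations remain open and were not tested.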
